A study of Rattus norvegicus with 26 samples.

How the data were processed

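Per the submitters' processing notes, arrays were processed in R 2.4.1 with affy 1.12.2, RMA and GCRMA 2.6.0, each of the 3 sets separately. The notes do not state which of RMA and GCRMA made the values. The deposited values are log2 expression values per the labels and were used as they are.

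Of 31099 probe sets 57 control probe sets were left out and 31042 tested. Of these 20826 had 1 gene symbol, 436 several and 9780 no gene named here. Among the probe sets with 1 symbol, 20758 had a gene ID that matched the current gene table. A gene with several probe sets (4525 genes) is shown by the one with the highest mean over the 26 arrays, which gave 14217 genes.

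Each set was fitted with limma 3.58.1 in R 4.3.3 (linear model and moderated t-test, two-sided), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Differences between effects were tested in 1 fit of both sets. Groups, tests and alternatives were chosen before the data were examined, apart from those said to be chosen later. Gene lists were tested by camera with an inter-gene correlation of 0.01, and beside it by camera with an estimated correlation and by fry. 26 lists were tested in adipose tissue and 32 in liver. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes.

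Named genes are the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between groups, up to 4 called members of each list by size (up to 2 where none was called), and the 5 largest differences in each direction. Arrays were regrouped in all 35 splits of 8 arrays, in 100 splits of 10 arrays and in 100 regroupings for each difference between effects.

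The procedure was tested on simulated data with 200 changed probe sets in 10 simulations. At a log2 change of 1 it recovered 76.6% in adipose tissue, 88.8% in liver at day 4, 90.2% at day 10 and 90.0% for the difference between liver effects, with 12.1, 7.6, 12.7 and 7.4 false calls on average. The changed probe sets were drawn from all those tested, most of which had a mean below 5. In the 3 sets the median within-group SD was 0.108, 0.0572 and 0.0582 over all probe sets. At a mean of at least 5 it was 0.210, 0.142 and 0.157. The noise was independent between probe sets. The rates thus do not give the recovery among probe sets with a mean of at least 5.

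Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.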

Results

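Gene expression was measured in inguinal white adipose tissue and in liver of male Long-Evans (Turku/AB) rats on an acute progressive feed restriction, in which the daily portion was made smaller step by step, and in control rats. Of the 26 arrays 13 were of restricted and 13 of control rats. The series description counts 1 array per rat, and the p-values treat every array as a separate animal. Liver and adipose tissue were both taken from the rats, so whether any rat gave both a day 4 liver and an adipose array is not settled by the labels. Adipose tissue was taken at day 4 from 4 restricted and 4 control rats, liver at day 4 from 4 restricted and 4 control rats, and liver at day 10 from 5 restricted and 5 control rats. Every rat received corn oil at 4 mL/kg on day 0. Over days 0 to 3 the short regimen gave 18, 12, 9 and 6 g of pelleted feed. The long regimen gave unlimited feed on day 0, and its portions of powdered feed went down from 16 g on day 1 to 1 g on day 9. Each portion was given at once during the light hours.

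The arrays reported 31042 probe sets for rat transcripts, of which 20826 were assigned to 1 gene symbol, for 14217 genes in all. The median log2 value of an array lay between 4.01 and 4.11 in adipose tissue and between 3.16 and 3.32 in liver. The lowest correlation between any 2 arrays of a set was 0.988 in adipose tissue, 0.990 in liver at day 4 and 0.983 in liver at day 10. The number of arrays, 4 or 5 per group, limits the precision. All changes are log2 values of restricted minus control rats, followed by their standard error (SE). Group values are means ± SD over the arrays of the group. Where 1 group lies near or below the median of its arrays, close to background, the size of a change is a lower bound. A gene is said to rise or fall where its adjusted p was below 0.05.

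**Figure D1:**
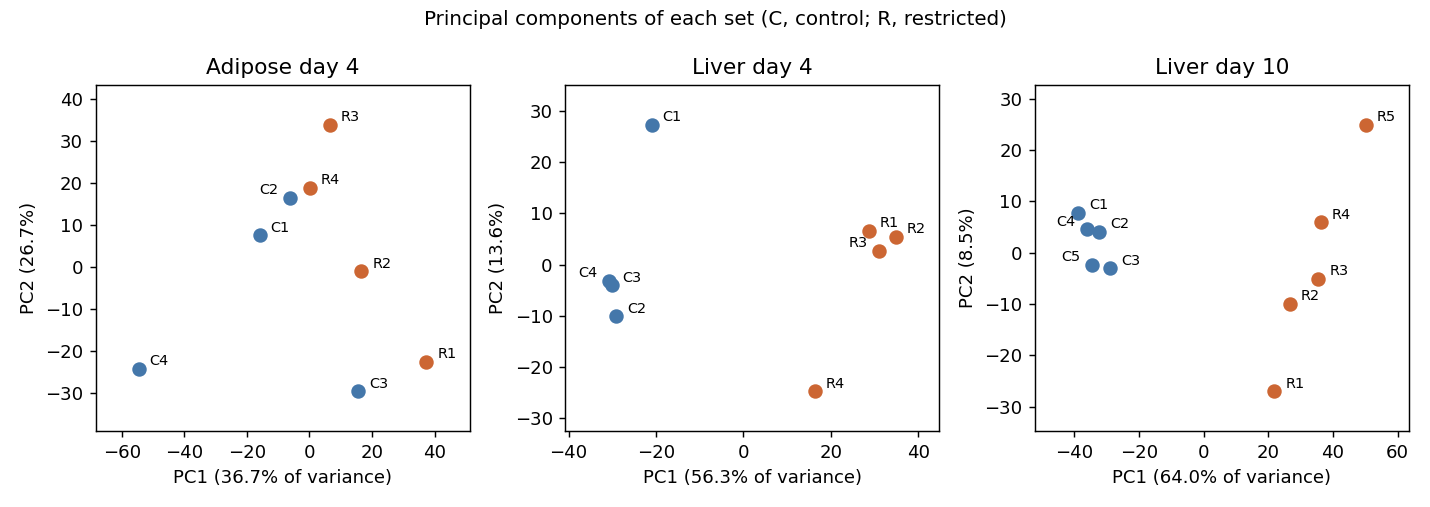
First and second principal components (PC1 and PC2, with the percent of variance) of the 8 adipose arrays, the 8 day 4 liver arrays and the 10 day 10 liver arrays, where each point is 1 array, C a control and R a restricted rat. PC1 parted the liver groups at both times (56.3% and 64.0% of variance), while in adipose tissue restricted array 4 (0.19) lay below control array 3 (15.6) on PC1.

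The first question was what the 4-day regimen did to the liver. Fat synthesis fell most. Scd, the desaturase that makes oleate, fell 110-fold, from 14.50 ± 0.22 to 7.71 ± 0.61 (log2 change -6.79, SE 0.30, n = 4 and 4, adjusted p = 0.000211). Fasn, the fatty acid synthase, fell by 4.15 (SE 0.30, adjusted p = 0.000633), and Decr1, a reductase of mitochondrial fat oxidation, rose by 1.84 (SE 0.07, adjusted p = 9.93e-05). In all, 1732 probe sets changed, 912 higher and 820 lower, among them 158 higher and 220 lower by 2-fold or more.

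Enzymes of fatty acid synthesis and desaturation fell as a group: 16 of 19 measured members fell and 0 rose, with a median of -1.60 (camera adjusted p = 4.19e-23, adjusted p = 0.137 with an estimated correlation). Adjusted over the list alone, 19 fell. Besides Scd and Fasn, the group held Pnpla3, a lipid droplet protein (-5.44, SE 1.08), the elongase Elovl6 (-4.34, SE 0.46) and Me1, the malic enzyme that supplies NADPH (-4.21, SE 0.49). Angptl8, an insulin-induced regulator of lipoprotein lipase, and the fatty acid carrier Fabp5 fell as well (-3.58, SE 0.50, and -4.58, SE 0.57). In glycolysis 4 of 14 members fell and 0 rose (median -0.20, camera adjusted p = 0.00621, adjusted p = 0.406 with an estimated correlation). The largest of these was Pklr, the liver pyruvate kinase (-3.31, SE 0.26), followed by Pgk1 (-0.39) and Pgam1 (-0.37). Cholesterol synthesis and uptake had a median of -0.85 with 2 of 19 members falling, or 8 adjusted over the list alone (camera adjusted p = 5.90e-06, adjusted p = 0.495 with an estimated correlation, fry adjusted p = 0.103). The list mean was low in restricted 3 and 4 (-0.69 and -0.96 from the mean of the set) and not in restricted 1 and 2 (0.15 and 0.03), against -0.03 and 0.32 in controls 1 and 2 and 0.66 and 0.52 in controls 3 and 4. The series lists arrays 1 and 2 of both groups apart from 3 and 4, and whether these are batches is not known here. The 2 called members were Dhcr7 (-1.95, SE 0.35) and Nsdhl (-0.85, SE 0.13), both enzymes of the later steps.

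Fatty acid oxidation rose: 15 of 20 members rose and 0 fell, with a median of 0.47 (camera adjusted p = 1.09e-13, adjusted p = 0.137 with an estimated correlation). Eci1, an isomerase of unsaturated fats, rose by 2.39 (SE 0.14), Cpt1a, which admits fatty acids to the mitochondrion, by 1.29 (SE 0.08), and Cpt2 by 1.16 (SE 0.11). Of 17 measured targets of the fatty acid sensor PPARalpha, 5 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.74, camera adjusted p = 0.00617, adjusted p = 0.318 with an estimated correlation). The omega-hydroxylases Cyp4a1 and Cyp4a3 rose by 1.42 and 1.39, while Plin2, a coat protein of lipid droplets, fell (-2.40, SE 0.29). Without control 3 the list of PPARalpha targets was not called by camera (adjusted p = 0.0754).

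**Figure D2:**
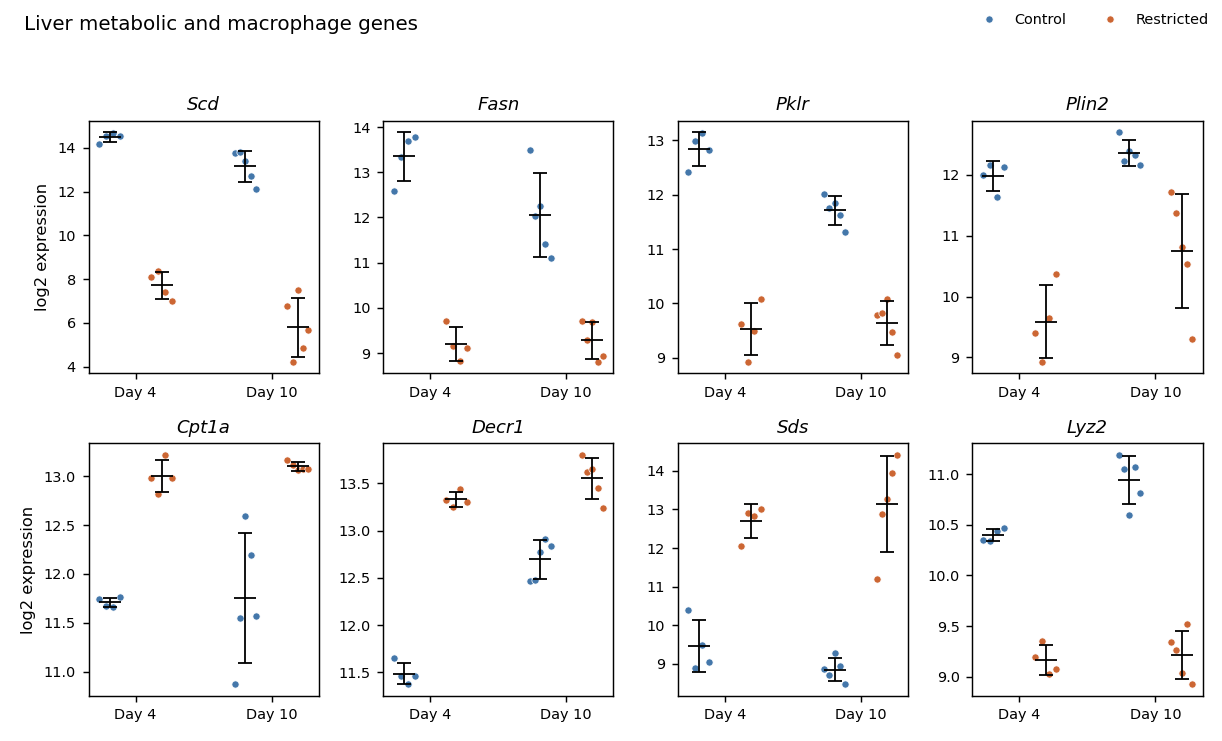
Log2 expression of 8 genes in liver at day 4 and day 10, where each point is 1 array (blue control, orange restricted) and bars show the mean ± SD. Scd, Fasn, Pklr, Plin2 and Lyz2 lay lower and Cpt1a, Decr1 and Sds higher in every restricted array than in every control array of the same day.

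Enzymes of amino acid breakdown and the urea cycle rose, 17 of 32 with 0 falling and 22 rising adjusted over the list alone (median 0.34, camera adjusted p = 1.18e-12, adjusted p = 0.159 with an estimated correlation). Sds, which deaminates serine to pyruvate, rose by 3.25 (SE 0.36), the urea cycle enzyme Asl by 1.52 (SE 0.08), and the aminotransferases Got1 and Gpt by 1.20 and 1.13. Irs2, an adaptor of the insulin receptor, rose by 3.18 (SE 0.57), and Igfbp1 and Igfbp2, carriers of insulin-like growth factors, by 2.87 (SE 0.49) and 2.29 (SE 0.41). Heat shock proteins rose in 6 of 12 members, or 10 adjusted over the list alone, for example Hsph1 (0.92) and Hsp90ab1 (0.60) (median 0.48, camera adjusted p = 7.50e-07, adjusted p = 0.137 with an estimated correlation). Chaperones of the endoplasmic reticulum moved the other way, with 5 of 19 falling and 1 rising, or 11 and 2 adjusted over the list alone (median -0.24, camera adjusted p = 1.46e-05, adjusted p = 0.318 with an estimated correlation). Pdia4 and Dnajb11 each fell by 0.65.

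Genes that are higher in female than in male rat liver rose in 4 of 8 cases (median 0.33, camera adjusted p = 0.00245, adjusted p = 0.235 with an estimated correlation). They were the repressor Cux2 (4.08, SE 0.24), the prolactin receptor Prlr (3.86, SE 0.83), the cofactor Trim24 (3.25, SE 0.28) and Cyp2a1 (0.46, SE 0.07). Of 8 male-biased genes 2 fell, Cyp2c11 (-0.45, SE 0.05) and Cyp2c13 (-0.27, SE 0.05), or 7 adjusted over the list alone with 1 rising (median -0.40, camera adjusted p = 0.000256, adjusted p = 0.318 with an estimated correlation). Collagens and other matrix genes fell in 6 of 25 cases, among them Col3a1 (-1.32) and Col6a3 (-1.22), or 11 adjusted over the list alone (median -0.38, camera adjusted p = 1.02e-06, adjusted p = 0.137 with an estimated correlation). Macrophage and Kupffer cell markers fell in 6 of 16 cases, or 11 adjusted over the list alone with 1 rising (median -0.57, camera adjusted p = 4.29e-07, adjusted p = 0.235 with an estimated correlation). They included the lysozyme Lyz2 (-1.23, SE 0.07), Clec4f of Kupffer cells (-0.72, SE 0.13) and the complement gene C1qc (-0.72, SE 0.09).

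Among genes outside these groups, the glutamate transporter Slc1a2 rose by 4.29 (SE 0.31), a lower bound since controls lay at the floor, the small GTPase Rab30 by 3.74 (SE 0.32) from 3.39 ± 0.31, and the sterol exporter Abcg5 by 3.47 (SE 0.31). Mmd2 (3.09, SE 0.59) and Bdh2 (3.04, SE 0.21) also rose. Inhba, a subunit of activin (-5.01, SE 0.45), the potassium channel Kcnj15 (-4.14, SE 0.45) and the phosphate transporter Slc34a2 (-3.57, SE 0.53) fell. Among clock genes 3 of 17 rose and 2 fell: Nfil3 (2.20), Per2 (1.35) and Tef (1.20) rose, and Npas2 (-2.90) and Clock (-0.83) fell (camera adjusted p = 0.0779). The remaining 19 lists were not called by camera either (camera adjusted p between 0.0779 and 0.986 over all 20, medians from -0.40 to 0.61). Of these 20 lists fry called clock genes and FOXO targets and autophagy genes (fry adjusted p = 0.0469 for each). Red blood cell, endothelial, lymphocyte and exocrine pancreas markers had 0 of their members called by limma. In 8 of the 20 lists the median, the mean and the camera direction did not all have the same sign, for example bile acid genes with a median of 0.03 and a mean of -0.06.

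Camera compares a list with all other genes. With an estimated correlation 0 of its 12 calls held, while fry, which tests whether the genes of a list move on balance one way and does not compare with other genes, called 13 lists, 11 of them shared with camera. Without control array 4 the number of probe sets was 1146 and without restricted array 1 it was 1091; scan records were not used here for this set, so a scan batch could not be checked.

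After the 10-day regimen the liver had again lost transcripts of fat synthesis. Scd fell 163-fold, from 13.15 ± 0.72 to 5.80 ± 1.34 (log2 change -7.35, SE 0.64, n = 5 and 5, adjusted p = 0.000182). Usp2, a deubiquitinating enzyme with a daily rhythm, rose by at least 6.71 (SE 0.22, adjusted p = 1.90e-06) from 3.33 ± 0.12, near background, and the clock factor Npas2 fell by 5.12 (SE 0.12, adjusted p = 2.22e-07), a lower bound, to 2.39 ± 0.05, near the floor of the arrays. Sds rose by 4.29 (SE 0.53, adjusted p = 0.000954), to 13.14 ± 1.23 from 8.85 ± 0.30. In all, 3471 probe sets changed, 1806 higher and 1665 lower, among them 341 higher and 405 lower by 2-fold or more.

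Of the fatty acid synthesis genes 13 of 19 fell and 0 rose, or 15 adjusted over the list alone (median -1.02, camera adjusted p = 1.94e-10, adjusted p = 0.190 with an estimated correlation). Elovl6 (-2.87, SE 0.59), Fasn (-2.77, SE 0.43) and Me1 (-2.26, SE 0.40) fell most after Scd. Cholesterol synthesis genes fell in 7 of 19 cases and rose in 2, with Cyp51 at -0.92 and Hsd17b7 at 0.72 (median -0.48, camera adjusted p = 5.93e-05, adjusted p = 0.190 with an estimated correlation). Fatty acid oxidation rose in 14 of 20 cases with 0 falling (median 0.41, camera adjusted p = 5.97e-06, adjusted p = 0.247 with an estimated correlation), led by Cpt1a (1.34, SE 0.28) and Eci1 (1.30, SE 0.33). Respiratory chain and citric acid cycle genes rose in 21 of 28 cases and fell in 1 (median 0.30, camera adjusted p = 7.93e-13, adjusted p = 0.190 with an estimated correlation), by modest amounts such as 0.58 for Suclg1 and 0.51 for Ogdh. Glucose synthesis rose in 5 of 12 cases and fell in 1 (median 0.30, camera adjusted p = 0.0176, adjusted p = 0.212 with an estimated correlation). Its largest members were Sds, the coactivator Ppargc1a (3.78, SE 0.55) and Got1 (2.18, SE 0.44), while the lactate dehydrogenase Ldha fell by 0.73. Sds and Got1 are also members of the list of amino acid breakdown, so the 2 lists are not separate evidence. The remaining called members changed by less than Ldha, and G6pc1 was not measured. Without restricted 3 this list was not called by camera (adjusted p = 0.0573). Triglyceride synthesis rose in 5 of 13 cases and fell in 1 (median 0.26, camera adjusted p = 0.0490, adjusted p = 0.190 with an estimated correlation). Lpin1, a phosphatidate phosphatase and coactivator, rose by 2.32 (SE 0.55), and the acyltransferase Gpam fell by 1.26 (SE 0.30). Triglyceride synthesis was not called without control 2, 3 or 4 (adjusted p = 0.0644, 0.0960 and 0.0648) or without restricted 2, 3 or 4 (adjusted p = 0.102, 0.0537 and 0.0740).

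Amino acid breakdown rose in 19 of 32 cases and fell in 1, or 24 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 3.55e-09, adjusted p = 0.247 with an estimated correlation). Asl rose by 1.98 (SE 0.22) and the tyrosine aminotransferase Tat by 1.89 (SE 0.31). Glucocorticoid-responsive genes rose in 7 of 17 cases and fell in 1: Igfbp1 (3.75, SE 0.45), the clock gene Per1 (2.90, SE 0.36), Fkbp5, which binds the glucocorticoid receptor complex (2.59, SE 0.43), and Tsc22d3 (2.12, SE 0.22) rose. This list was not called by camera (median 0.49, adjusted p = 0.0673) and was called by fry (adjusted p = 0.00282), with medians of 0.03 on scan day 1 and 0.62 on scan day 2. Heat shock proteins rose in 7 of 12 cases (median 0.33, camera adjusted p = 1.65e-05, adjusted p = 0.190 with an estimated correlation), for example Hspa1a (1.85) and Dnajb1 (1.03). Endoplasmic reticulum chaperones fell in 12 of 19 cases and rose in 2 (median -0.49, camera adjusted p = 1.36e-05, adjusted p = 0.247 with an estimated correlation). Hyou1 (-1.44) and Sdf2l1 (-1.39) fell, while Edem1 and Herpud1, which act in the disposal of misfolded proteins, rose by 1.34 and 1.31. Acute phase proteins fell in 9 of 17 cases and rose in 2 (camera adjusted p = 0.000291, adjusted p = 0.190 with an estimated correlation). Their median was -0.16 but their mean 0.19 (0.12 without control 1 and 0.11 without control 4), with Orm1 at -0.70 and the lipopolysaccharide binder Lbp at 0.66.

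**Figure D3:**
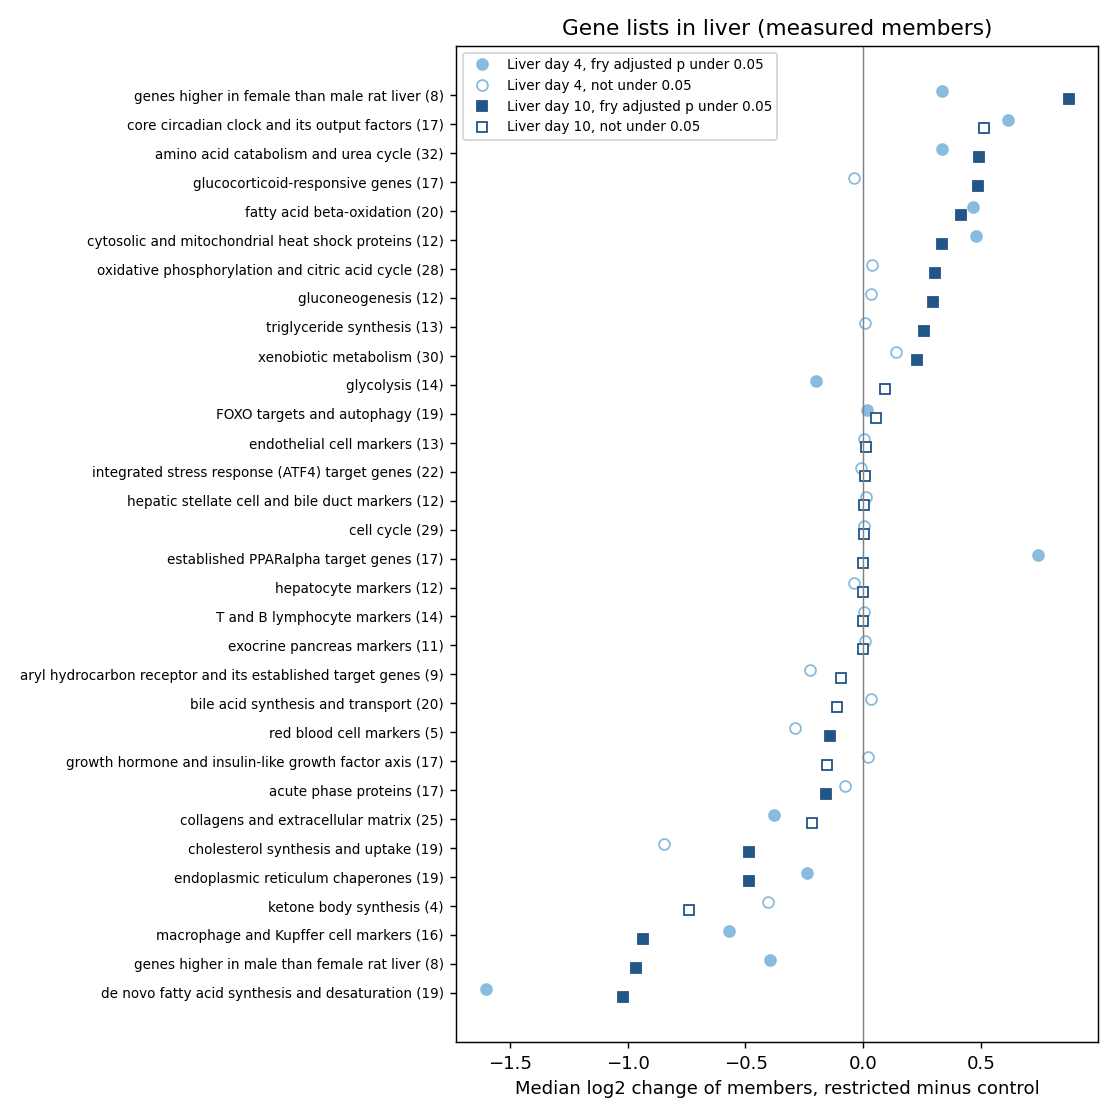
Median log2 change of the measured members (numbers in brackets) of each gene list in liver, on the x axis, with circles for day 4 and squares for day 10, filled where fry's adjusted p was under 0.05. Fatty acid synthesis (-1.60 and -1.02) and macrophage markers (-0.57 and -0.94) lay below 0 and amino acid breakdown (0.34 and 0.49) above 0 at both times.

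Female-biased genes rose in 5 of 8 cases (median 0.87, camera adjusted p = 0.000525, adjusted p = 0.190 with an estimated correlation), led by Trim24 (4.75, SE 0.49), Prlr (4.55, SE 0.84), Cux2 (4.01, SE 0.34) and Cyp2c12 (1.35, SE 0.22). Male-biased genes fell in 5 of 8 cases, or 6 adjusted over the list alone (median -0.96, camera adjusted p = 1.18e-05, adjusted p = 0.190 with an estimated correlation). They included the pheromone carrier Obp3 (-2.40, SE 0.13), the carbonic anhydrase Car3 (-1.94, SE 0.53), Cyp2c13 (-1.06, SE 0.22) and Cyp2c11 (-0.87, SE 0.14). In the growth hormone and insulin-like growth factor axis 3 of 17 members rose and 3 fell (camera adjusted p = 0.301). Igfbp2 rose by 2.85, while the growth hormone receptor Ghr and its signal carrier Stat5b fell (-1.16, SE 0.17, and -1.24, SE 0.11). Of 30 xenobiotic metabolism genes 9 rose and 5 fell (camera adjusted p = 0.209, fry adjusted p = 0.00603), with medians of -0.01 and 0.30 on the 2 scan days. Por, the electron donor of microsomal P450 enzymes, rose by 3.60 (SE 0.23), and the xenobiotic receptors Nr1i2 and Nr1i3 rose by 1.54 and 1.09.

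Clock genes moved in both directions, 8 of 17 up and 3 down (camera adjusted p = 0.0673). Fry found the list changed in either direction (mixed adjusted p = 1.30e-09) but not on balance one way (adjusted p = 0.811). The mixed result does not set clock genes apart, since most lists had one below 0.05, for example hepatocyte markers (fry mixed adjusted p = 8.79e-06). Only cell cycle, lymphocyte, endothelial and exocrine pancreas lists did not. Dbp, an output factor, rose by 4.27 (SE 0.60), Per2 by 3.48 (SE 0.30), Per1 by 2.90 (SE 0.36) and Tef by 2.64 (SE 0.32). Bmal1 (-2.27, SE 0.27) and Clock (-0.90, SE 0.14), which drive the period genes, fell along with Npas2. On the 2 scan days all 11 called clock genes moved the same way, for example Per2 by 3.45 and 3.54.

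**Figure D4:**
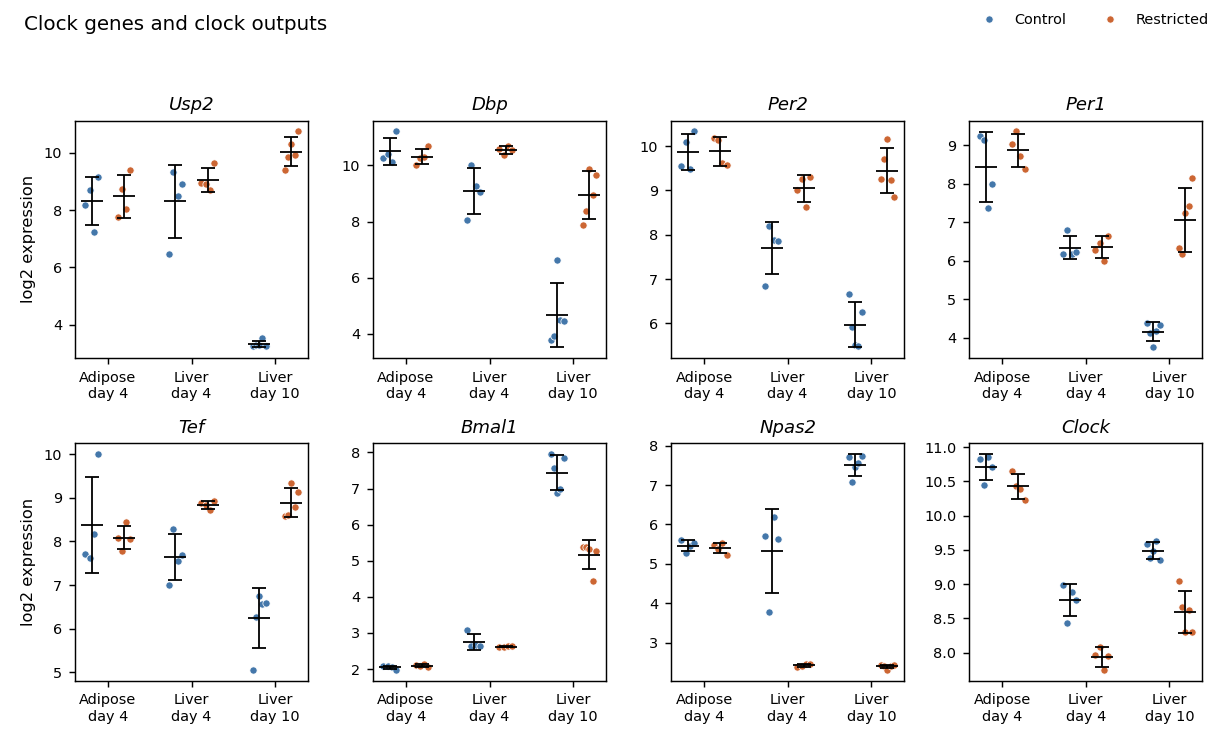
Log2 expression of Usp2, a gene with a daily rhythm, and of 7 clock genes and clock outputs in adipose tissue at day 4 and in liver at day 4 and day 10, where each point is 1 array (blue control, orange restricted) and bars show the mean ± SD. At day 10 Usp2, Dbp, Per2, Per1 and Tef lay higher and Bmal1, Npas2 and Clock lower in restricted liver, while in adipose tissue 0 of the 17 clock list genes were called.

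Macrophage and Kupffer cell markers fell in 11 of 16 cases with 0 rising, or 12 adjusted over the list alone (median -0.94, camera adjusted p = 4.38e-10, adjusted p = 0.190 with an estimated correlation). The falls included Lyz2 (-1.72, SE 0.14), the macrophage surface protein Adgre1 (-1.67, SE 0.14), the lysosomal protein Cd68 (-1.13, SE 0.14) and Clec4f (-1.12, SE 0.11). Red blood cell markers fell in 2 of 5 cases (median -0.14, camera adjusted p = 0.0183, adjusted p = 0.247 with an estimated correlation). These were Alas2, which starts haem synthesis in red cells (-3.80, SE 0.58), and the globin Hbb (-2.55, SE 0.38). Matrix genes fell in 4 of 25 cases and rose in 1, with Lox, which crosslinks collagen, at -4.49 (SE 0.26) and the proteoglycan Dcn at 1.62 (SE 0.44) (median -0.22, camera adjusted p = 0.0183, adjusted p = 0.651 with an estimated correlation). The matrix list was not called without control 4 (adjusted p = 0.107) or restricted 5 (adjusted p = 0.0602). Endothelial and lymphocyte markers had 0 members called by limma, with medians of 0.01 and -0.00162. Of 12 stellate cell and bile duct markers 2 rose and 1 fell (camera adjusted p = 0.900), and of 12 hepatocyte markers 1 rose and 2 fell (camera adjusted p = 0.454).

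Other large changes were rises of Noct (6.05, SE 0.79), the steroid hydroxylase Cyp17a1 (5.67, SE 0.48), Zfp354a (4.20, SE 0.26), Akr1b7 (4.19, SE 0.68) and Ablim3 (4.03, SE 0.37). Falls were seen in Poteml2 (-5.84, SE 0.26), Inhba (-5.69, SE 0.58), Stac3 (-5.37, SE 0.79), the organic anion transporter Slc22a8 (-5.06, SE 0.32), the taurine transporter Slc6a6 (-4.42, SE 0.49), Slc34a2 (-4.37, SE 0.47) and the ketosteroid reductase Akr1c3 (-4.26, SE 0.39). The sizes are lower bounds for Noct, Cyp17a1, Akr1b7 and Ppargc1a, which lay near background in controls, and for Poteml2, Inhba, Akr1c3 and Alas2, which did so in restricted rats. The 17 lists without a camera call had camera adjusted p between 0.0673 and 0.935 and medians from -0.74 to 0.51. Among them fry called glucocorticoid-responsive and xenobiotic metabolism genes (fry adjusted p = 0.00282 and 0.00603). For bile acid genes, the growth hormone axis and hepatocyte markers the median and mean had different signs, as they had for PPARalpha targets, stress response and cell cycle genes.

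The day 10 arrays were scanned on 2 days that each held both groups (3 controls and 2 restricted, then 2 and 3). With scan day as a block 3209 probe sets and 14 lists were called, against 567 and 14 on day 1 alone and 1240 and 13 on day 2 alone. All 3471 called probe sets and all 111 named called genes had the same sign on both days (r = 0.937 across called probe sets, which are not independent replicates), as had the medians of 14 of the 15 called lists. The exception was the matrix list, at 0.03 on day 1 and -0.35 on day 2. The probe sets, genes and lists were called in the fit of both days, so the same sign on each day was nearly given. The firmer check is the fit with scan day as a block, where 3068 of its 3209 calls were among the 3471. With an estimated correlation 0 of the 15 camera calls held, while fry called 16 lists, 14 of them shared with camera.

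Liver changes at the 2 times overlapped. Of the 1732 probe sets called at day 4, 70.3% were also called in the same direction at day 10: 646 were higher at both times, where 53.1 would be shared by chance, and 571 lower, where 44.0 would. Only 4 were called in opposite directions. Across 14217 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.703 and a Spearman rho of 0.581.

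The next question was where the effect of the 2 liver regimens differed, tested as the day 10 change minus the day 4 change. It differed for 203 probe sets, 117 more positive and 86 more negative at day 10, among 2607 with an unadjusted p below 0.05. Usp2 changed by 5.96 more at day 10 (SE 0.62, adjusted p = 0.000548). Its restricted means were 9.06 ± 0.41 at day 4 and 10.04 ± 0.51 at day 10, while its control means were 8.31 ± 1.26 and 3.33 ± 0.12, so the difference lay mainly in the controls. Lpin1 fell at day 4 (-1.67) and rose at day 10 (2.32), a difference of 4.00 (SE 0.72, adjusted p = 0.0203). Zfp354a (5.81, SE 0.81, control means 10.13 at day 4 and 5.88 at day 10), Cyp17a1 (4.45, SE 0.66) and Akr1b7 (4.10, SE 0.79) were also more positive at day 10. Stac3 (-5.22, SE 0.96), Lox (-3.75, SE 0.49), Akr1c3 (-3.57, SE 0.48), the sulfotransferase Sult1c2 (-2.88, SE 0.57) and the arrestin family member Arrdc3 (-2.85, SE 0.41) were more negative. Sult1c2 was called at day 4 only, with a rise of 2.08. For Usp2, Cyp17a1, Akr1b7 and Akr1c3 a group at day 10 lay near background, so these differences are bounds rather than exact sizes.

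Among gene groups, camera and fry both found a higher change at day 10 for oxidative phosphorylation and the citric acid cycle (median difference 0.27, camera adjusted p = 8.11e-28, adjusted p = 0.101 with an estimated correlation) and for glucocorticoid-responsive genes (0.87, camera adjusted p = 0.000323, adjusted p = 0.108 with an estimated correlation). Glycolysis (0.36, adjusted p = 0.105 with an estimated correlation), glucose synthesis (0.47, adjusted p = 0.122) and triglyceride synthesis (0.11, adjusted p = 0.129) followed. The 203 rested on single arrays: without 1 array the count was 135, 134, 313 and 125 for day 10 control 2, control 4, restricted 1 and restricted 3, and 122, 104, 110 and 122 for day 4 control 2, control 4, restricted 1 and restricted 3. With both sets quantile normalised together 190 were called, 168 of them among the 203, so different scaling of the sets was not the source of most of them, though this does not undo the separate summarising of the arrays. The form of the feed, the length of the regimen and the hour of killing, which the labels do not give, cannot be told apart here. The hour matters since Usp2, which has a daily rhythm, differed between the controls of the 2 times.

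**Figure D5:**
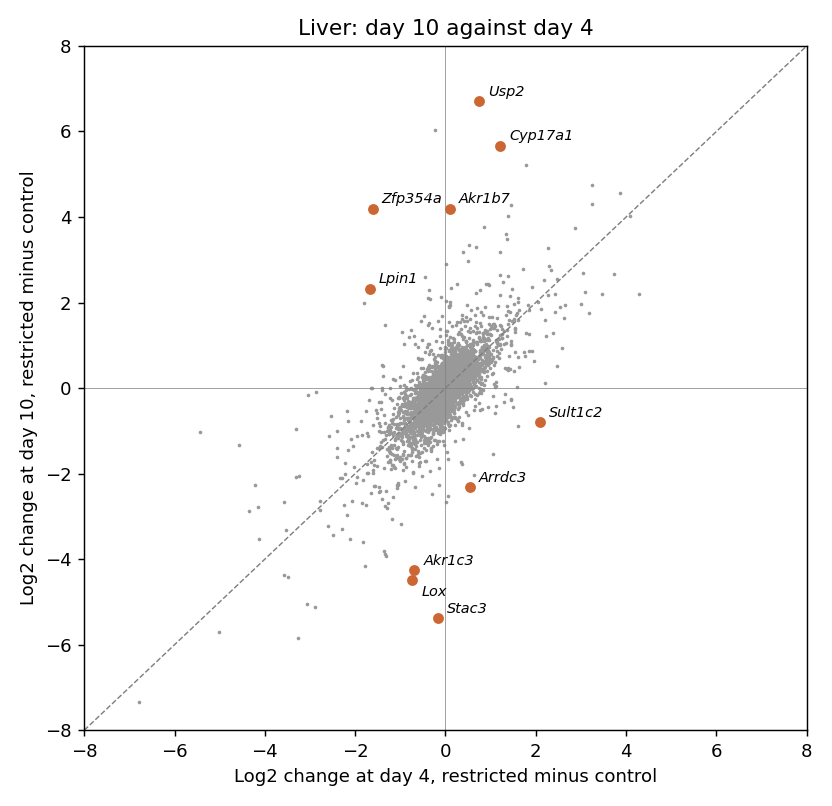
Log2 change (restricted minus control) in liver at day 10, y axis, against day 4, x axis, where each grey point is 1 gene or probe set, the dashed line marks equal change and orange points are the 10 genes named for a difference between the times. Most genes with large changes lay on the same side of 0 at both times (r = 0.703 across genes), whereas Usp2 and Zfp354a lay far above the line and Stac3 far below it.

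In adipose tissue at day 4 few genes changed. Oxtr, the oxytocin receptor, fell by 5.29 (SE 0.37, n = 4 and 4, adjusted p = 0.0258), a lower bound, from 7.17 ± 0.80 to 1.87 ± 0.03, the floor of the arrays. Irs2 rose by 1.22 (SE 0.10, adjusted p = 0.0258), from 9.22 ± 0.11 to 10.44 ± 0.19. Elovl5, an elongase of unsaturated fats, fell by 0.70 (SE 0.07, adjusted p = 0.0325). In all 17 probe sets changed, 5 higher and 12 lower, for 15 genes. At an unadjusted p below 0.05 there were 2387, or 7.69% of those tested.

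The other rises were Adgrv1, an adhesion receptor (1.58, SE 0.14), the nucleotide receptor P2ry2 (1.21, SE 0.10), Zfp609 (0.87, SE 0.08) and Mtus1 (0.44, SE 0.04). The other falls were the microtubule kinase Dclk1 (-1.16, SE 0.09), Nrep (-1.07, SE 0.09), the junction protein Cgnl1 (-0.86, SE 0.08), Pagr1 (-0.84, SE 0.07) and Anxa6, a calcium-dependent membrane binder (-0.61, SE 0.05). Tbl1x, a corepressor subunit (-0.52, SE 0.04), Copz2, a vesicle coat subunit (-0.39, SE 0.04), and Stt3b, a subunit of the glycosylation complex (-0.30, SE 0.03), fell less.

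Several metabolic groups lay lower with 0 or 1 of their members passing by limma. Respiratory chain and citric acid cycle genes were negative in 28 of 28 cases (median -0.37, camera adjusted p = 1.57e-13, adjusted p = 0.425 with an estimated correlation), with 0 called by limma and 15 falling adjusted over the list alone. Fatty acid synthesis had a median of -0.47, with 1 of 19 members falling, or 6 adjusted over the list alone (camera adjusted p = 1.30e-06, adjusted p = 0.425 with an estimated correlation). Glycolysis (-0.33, 5 of 14 falling adjusted over the list alone, camera adjusted p = 2.62e-05, adjusted p = 0.425 with an estimated correlation) and cholesterol synthesis (-0.19, 7 of 19, camera adjusted p = 0.000293, adjusted p = 0.425 with an estimated correlation) were lower too. Triglyceride synthesis (-0.27, adjusted p = 0.526 with an estimated correlation), lipolysis (-0.16, adjusted p = 0.664), fatty acid oxidation (-0.23, adjusted p = 0.721) and adipocyte markers (-0.17, adjusted p = 0.548) were called lower by camera at 0.00406, 0.00837, 0.00837 and 0.00166. Fatty acid oxidation and lipolysis were not called without control 4 (adjusted p = 0.238 and 0.328), where their mean changes went from -0.19 to -0.06 and from -0.29 to -0.16, or without restricted 1 (adjusted p = 0.169 and 0.0799). The mean change of triglyceride synthesis went from -0.30 to -0.19 without control 4 (adjusted p = 0.0174). Slc2a4, the insulin-regulated glucose transporter, had a change of -2.57 (SE 0.33, adjusted p = 0.0956), which did not pass.

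Glucocorticoid-responsive genes lay higher (median 0.38, camera adjusted p = 0.00156, adjusted p = 0.425 with an estimated correlation), with 4 of 17 rising adjusted over the list alone. Neither Pdk4, which holds back glucose oxidation (1.61, adjusted p = 0.206), nor the metallothionein Mt2A (1.55, adjusted p = 0.193) passed. FOXO targets and autophagy genes (0.05, camera adjusted p = 0.00201, adjusted p = 0.425 with an estimated correlation) had Irs2 as their only called member. Endoplasmic reticulum chaperones (-0.21, camera adjusted p = 0.00101, adjusted p = 0.548 with an estimated correlation) and matrix genes (-0.25, camera adjusted p = 0.00837, adjusted p = 0.425 with an estimated correlation) were lower. Matrix genes were not called without control 2 or 3 (adjusted p = 0.0521 and 0.0737). Of the cell type markers, lymphocyte genes were slightly higher (0.05, camera adjusted p = 0.0172, adjusted p = 0.721 with an estimated correlation), but not called without control 4 or restricted 1 (adjusted p = 0.467 and 0.0686). Hepatocyte genes were lower (-0.29, camera adjusted p = 0.00895, adjusted p = 0.664 with an estimated correlation), with Cps1 at -3.43 and Ttr at -2.41, neither of which passed. Control 1 stood apart for this list (1.23 from the mean of the set, other controls 0.04 to 0.14), and without it the mean change was -0.48 instead of -0.76 (adjusted p = 0.0354). Macrophage, red cell, skeletal muscle, epithelial and endothelial markers were among the 12 lists without a call (p between 0.0596 and 0.954, medians from -0.29 to 0.16). In 5 of these, among them thermogenic genes, the median and the mean had different signs.

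With an estimated correlation 0 of the 14 camera calls held, and fry called 0. The 17 probe sets rested on single arrays: without control 1, 2, 3 or 4 the count was 1, 2, 0 or 15, and without restricted 1, 2, 3 or 4 it was 3, 0, 0 or 0. All adipose arrays were scanned on 1 day, but controls and restricted rats were run on different fluidics stations, so the station and the group cannot be told apart.

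The change under the 4-day regimen differed between the 2 tissues for 1057 probe sets, in a test that treats all 16 arrays as separate rats, 387 with a more positive and 670 with a more negative change in adipose tissue than in liver. Scd was not called in adipose tissue (-0.03, SE 0.81, adjusted p = 0.983), and its change was 6.76 higher there than in liver (SE 0.90, adjusted p = 0.000989). The adipose value rested on restricted 3 (9.87, against 12.73 to 13.46 in the other restricted arrays), without which it was 0.77. Fabp5 (4.99, SE 0.60), Kcnj15 (4.15, SE 0.47), Elovl6 (3.97, SE 0.53) and Gulo, the last enzyme of vitamin C synthesis (3.95, SE 0.40), followed. Gulo fell by 1.07 in liver and had 2.88 in adipose tissue, which did not pass (adjusted p = 0.0956). Prlr (-3.87, SE 0.87), Cux2 (-4.001, SE 0.26) and Slc1a2 (-4.28, SE 0.33) rose in liver and were not called in adipose tissue. Both groups lay near background in adipose tissue for Kcnj15, Cux2 and Slc1a2 (means from 1.82 to 3.04). Oxtr (-5.30, SE 0.38) fell in adipose tissue to the floor, so its difference is a bound, and lay at the floor in both liver groups (1.83). Rup2 (-4.63, SE 0.93) was called for the difference alone, since its change of -4.67 in adipose tissue did not pass (adjusted p = 0.196). Probe sets called in neither tissue alone made up 298 of the 1057. The test pools the spread of both tissues, though it was larger in adipose tissue (median within-group SD 0.193, against 0.140 in liver).

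By both camera and fry the difference covered fatty acid synthesis (median difference 1.28, camera adjusted p = 2.71e-14, adjusted p = 0.204 with an estimated correlation), fatty acid oxidation (-0.71, camera adjusted p = 6.41e-15, adjusted p = 0.204 with an estimated correlation) and heat shock proteins (-0.59, adjusted p = 0.204 with an estimated correlation). It also covered macrophage markers (0.57, adjusted p = 0.223 with an estimated correlation), oxidative phosphorylation and the citric acid cycle (-0.42, adjusted p = 0.382) and clock genes (-0.81, adjusted p = 0.382). Of the 17 adipose calls 2 were shared with liver at day 4 in the same direction, 1 higher (0.147 by chance) and 1 lower (0.317 by chance), and 1 was opposite. With liver at day 10, 1 higher (0.291 by chance) and 4 lower (0.644 by chance, Fisher exact p = 0.00288 across probe sets, which are not independent) were shared, and 1 was opposite. Across 14217 genes, which are not independent replicates, the log2 changes in adipose tissue had an r of 0.0994 with those in liver at day 4 and of 0.0701 with those at day 10.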

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

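The tests of adipose spread, smooth muscle, macrophage markers, clock genes and the regroupings with the shared effect subtracted were chosen after the results they concern were seen.

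Of 624 groups of arrays, 49 held a single array far from the rest by Dixon's test, where chance gives about 1 in 20 groups, or 31.2. All values are log2. In adipose tissue they were restricted 3 for Mt2A (11.68), Slc2a4 (6.61) and Cps1 (3.76), control 4 for Top2a (3.62), Col15a1 (13.22) and Cd2 (2.31), and restricted 1 for Cd2 (4.17). Control 3 for Sdf2l1 (8.05), control 2 for Mki67 (5.81) and control 1 for Cd4 (7.39) lay apart too.

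In liver at day 4, restricted 4 lay apart for Fabp5 (4.31), Ces2c (8.23), Igfbp2 (9.45), Shmt2 (10.97) and Suclg1 (11.61), the most of any array. Restricted 3 did so for Cyp2c11 (13.83), Lpin2 (8.94) and Rgs5 (3.37), restricted 2 for Cyp3a23-3a1 (14.02) and restricted 1 for Col6a3 (5.16). Among controls these were control 1 for Irs2 (7.32) and Hsph1 (8.07), control 2 for Alas2 (8.97) and Hbb (14.27), control 3 for Coro1a (4.48) and control 4 for Ccnd1 (9.33).

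In liver at day 10, restricted 3 lay apart for Npas2 (2.30), Alas2 (4.41) and Hbb (11.90), restricted 1 for Nfe2l2 (11.06), Hyou1 (5.25) and Cd4 (2.38), restricted 5 for Hsd17b7 (9.76) and Cyp2c13 (12.21), and restricted 2 for Igfbp2 (11.34). Among controls these were control 3 for Dbp (6.65), Asl (12.03) and Tsc22d3 (9.51), control 5 for Stat5b (6.83), Hsp90ab1 (13.68) and Prss1 (3.76), control 4 for Usp2 (3.53) and control 2 for Nr0b2 (8.12).

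Of the marker lists, given as distance from the mean of the set, macrophage markers lay apart in day 10 restricted 4 (-0.13), lymphocyte markers in adipose restricted 1 (0.15) and hepatocyte markers in adipose control 1 (1.23). Red cell markers did so in day 4 control 2 (1.30) and day 10 restricted 3 (-0.18). The 3' minus 5' signal of actin was 2.17 in adipose restricted 2.

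The effect differed between the liver regimens for 203 probe sets, with Usp2 at 5.96, Zfp354a at 5.81, Cyp17a1 at 4.45, Akr1b7 at 4.10 and Lpin1 at 4.00 more positive at day 10. Arrdc3 (-2.85), Sult1c2 (-2.88), Akr1c3 (-3.57), Lox (-3.75) and Stac3 (-5.22) were more negative. The list medians differed by 0.465 for glucose synthesis, 0.358 for glycolysis, 0.872 for glucocorticoid-responsive genes, 0.267 for oxidative phosphorylation and 0.112 for triglyceride synthesis.

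The effect differed between adipose tissue and liver at day 4 for 1057 probe sets, with Scd at 6.76, Fabp5 at 4.99, Kcnj15 at 4.15, Elovl6 at 3.97 and Gulo at 3.95 more positive in adipose tissue. Prlr (-3.87), Cux2 (-4.001), Slc1a2 (-4.28), Rup2 (-4.63) and Oxtr (-5.30) were more negative. The list medians differed by -0.708 for fatty acid oxidation, 1.28 for fatty acid synthesis, -0.808 for clock genes, -0.586 for heat shock proteins, -0.421 for oxidative phosphorylation and 0.573 for macrophage markers.

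Arrays were also split into groups that ignore the diet. The count of called probe sets was reached by 1 of 35 splits in adipose tissue, the real one (17, highest other 1). In liver it was reached by 1 of 35 at day 4 (1732, highest other 19) and 1 of 100 at day 10 (3471, highest other 1). Chance is thus an unlikely source in liver, though 1 of 35 is the lowest share that 35 splits can give. In adipose tissue chance is not excluded, since the count was 0 without control 3 or restricted 2, 3 or 4. The splits also cannot tell diet from fluidics station there. The camera list counts were reached by 4 of 35 splits in adipose tissue (14, highest other 15), 4 of 35 in liver at day 4 (12, highest other 13) and 7 of 100 at day 10 (15, highest other 17), so chance cannot be excluded for them. With fry the counts were 0 (highest other split 2), 13 (highest other 3) and 16 (highest other 2). Fry was planned beside camera, which remains the main list test, and was given more weight, as in the figure of lists, after these splits were seen. With array weights the 1187 adipose calls were reached by 12 of 35 splits (highest other 9015), so chance cannot be excluded.

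For the day 10 minus day 4 difference, 4 of 100 splits within the sets called at least 203, the highest other 13446, and 3 of 100 did so once the shared effect was subtracted, the highest other 13699. A split that calls many times the real count points to a structure of the samples, whose nature was not tested, and 98.8% of those 13446 calls had a mean below 5 with a median size of 0.0653. Among probe sets with a mean of at least 5, 401 were called and 2 of 100 splits reached this, the highest other 1124. For adipose minus liver, 1 of 100 splits reached 1057 (highest other 756), and 1 of 100 with the shared effect subtracted (highest other 48).

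The low number of calls in adipose tissue may come from larger differences between rats or pieces of tissue. Over 9236 probe sets at 5 or more in both tissues the median within-group SD was 0.193 in adipose tissue and 0.140 in liver, a ratio of 1.38, as larger spread predicts. Smooth muscle marker means per array ranged from -1.26 to 2.03, and with them as a covariate 35 probe sets were called. Of 100 random orders of these means 10 called as many, the highest other 646, so tissue content could not be told from chance. A smaller response of adipose tissue remains possible.

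The lower macrophage markers in restricted liver could reflect the make-up of the tissue. Endothelial markers at 5 or more had a median of 0.0135 at day 10 against -0.937 for macrophage markers, which speaks against a lower share of all cells other than hepatocytes. Clec4f, found on resident Kupffer cells and not in blood, fell (-1.12), which speaks against less blood as the whole source. Red cell markers fell too at day 10 (Hbb -2.55, Alas2 -3.80), so less blood could still have lowered markers that blood cells share. Whether there were fewer Kupffer cells or less of these transcripts per cell stays open.

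The clock genes that moved in opposite directions at day 10 may reflect a shifted clock phase. All 11 called genes moved the same way on both scan days. They were called in the fit of both days, so this was nearly given and cannot decide on scan day as a source. Of the 11, 3 fell, so it was no rise of the whole list. All 9 positive-limb, period and D-box genes were called in the directions of a phase shift, but these directions had been seen when the test was written, so it could not bear a shift out. A phase shift thus stays open, and feeding in the light hours and the hour of killing cannot be told apart here.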

How the results depend on the processing

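The settings with 1 scan day only, with the smooth muscle covariate and without pairs of arrays were chosen after the results were seen.

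The 17 adipose calls depended on the processing: 0 with replicate number as a block (a pairing the labels do not give), 29 among probe sets with a mean of at least 5, 9 after quantile normalisation (5 higher, 4 lower), 3 after median centring (0 higher, 3 lower), 1187 with array weights (348 higher, 839 lower), 1389 in 1 fit of 26 arrays, 35 with the smooth muscle covariate, 1 without controls 1 and 4, and 0 to 15 leaving out 1 array. Fewer arrays cost precision, and otherwise the cause was not tested. Its 14 lists became 8 at a mean of at least 5, 0 with an estimated correlation, 0 by fry, 9 without controls 1 and 4, and 11 to 16 leaving out 1 array.

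In liver at day 4 the 1732 calls became 987 with the replicate block, 2723 with array weights and 1091 to 1744 leaving out 1 array; the cause was not tested. At day 10 the 3471 became 567 on scan day 1 only and 1240 on scan day 2 only, which hold fewer arrays, and 2841 to 3442 leaving out 1 array. With an estimated correlation the lists were 0 at both times, and leaving out 1 array 12 to 14 and 13 to 17.

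The 203 for day 10 minus day 4 became 34 with the replicate block, 401 at a mean of at least 5 and 104 to 313 leaving out 1 array. The 1057 for adipose minus liver ranged from 761 to 1205 leaving out 1 array. The 1217 probe sets called in the same direction, liver day 4 and liver day 10, ranged from 806 (without day 4 restricted 1) to 1189 leaving out 1 array, and r from 0.662 to 0.715 (0.722 at a mean of at least 5). Adipose tissue and liver at day 4 shared 0 to 3 calls instead of 2. The Pearson r of log2 changes across genes, adipose day 4 and liver day 4, was 0.148 at a mean of at least 5 and 0.0790 to 0.126 leaving out 1 array.

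No gene reversed under these settings in a comparison in which it was named and called. Of the lists called by camera, the day 10 matrix list alone reversed, with a median of 0.03 on scan day 1 only (adjusted p = 0.990); the cause was not tested. Signal over background limits the rest: 55.1%, 66.1% and 64.4% of tested probe sets had a mean below 5 in adipose tissue, liver at day 4 and liver at day 10, against 5.88%, 3.75% and 5.01% of those called.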

Other observations

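The interferon list at day 10, the tests of liver transcripts in 1 adipose array and those of Cish were chosen after the results were seen, while the interferon tests at day 4 and in adipose tissue were written before their results.

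Interferon-stimulated genes stood out among the falls in liver at day 10, and a list of them was then made, with 26 measured. Of these 19 fell (median -1.41, camera p = 3.31e-15, p = 0.0157 with an estimated correlation, fry p = 1.24e-05), with medians of -1.28 and -1.26 on the 2 scan days. The largest were Cxcl9 (-3.30), Igtp (-2.75), Usp18 (-2.74), Rsad2 (-2.70) and Irf7 (-2.64). For the 21 left without those first noticed the median was -1.03 with 14 falling, and camera and fry still called the list lower, though each p of a list here is unadjusted. Macrophage and Kupffer cell markers fell in the same livers (medians -0.57 at day 4 and -0.94 at day 10), so a lower interferon response was not told from fewer cells that carry these transcripts. In liver at day 4 the median was -0.776 with 6 genes falling (camera p = 8.73e-12, p = 0.0554 with an estimated correlation, fry p = 0.00424). In adipose tissue it was -0.329 with 0 called by limma (camera p = 2.03e-07, p = 0.0534 with an estimated correlation, fry p = 0.0182). The list mean of restricted against control rats was 7.78 ± 0.06 and 8.19 ± 0.22 in adipose tissue, 6.48 ± 0.33 and 7.40 ± 0.24 in liver at day 4, and 6.18 ± 0.27 and 7.53 ± 0.20 at day 10 (exact permutation p = 0.0286, 0.0286 and 0.00794, the smallest possible for n = 4 and 5 per group). These means are over all 26 genes, with those first noticed at day 10 included, so the day 10 value was nearly given and is no separate support.

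Adipose control 1 had high values of some hepatocyte transcripts (Cps1 8.50, Ttr 8.03, Serpina1 6.43 and Ahsg 5.66) and not of others: Apoa1 was 3.07, F2 2.66, Apob 2.39, Serpinc1 2.15 and Hnf4a 2.07, and Alb, at 14.19, was below control 4 (14.59). Controls 2 to 4 also had more Cps1 (5.28 to 6.30) and Ttr (5.42 to 6.14) than every restricted array (2.59 to 3.76 and 3.57 to 4.51). The higher Cps1 and Ttr were thus not peculiar to control 1. Of the 50 genes most abundant in liver and below 5 in the other adipose arrays, 31 were highest in that array, less than the bound of 80% set for liver RNA carried into it, and the most in any other array was 13. The choice of genes below 5 in every array but control 1 favoured control 1 in this count, so it left a trace of liver RNA unsettled. Liver RNA as the source of the Cps1 and Ttr signal is spoken against: at the liver share that Ttr needs, these 50 genes would have a median of 7.19, but it was 3.03 in that array, and 2 of the 50 came within 2 log2 units of the level needed (median distance -3.99, SD 0.94).

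Cish, which a growth hormone pulse induces, was high at day 4 in control 1 (9.83) and in restricted 1, 2 and 3 (9.33, 9.29 and 9.53) and low in the other 4 livers (3.22 to 4.28). Socs2, which a pulse also induces, was 6.54 to 7.65 in the 4 livers with high Cish and 5.08 to 6.18 in the other 4, and among restricted livers Bcl6 was 9.15 in the one with low Cish and 5.08 to 6.78 in the rest. Among controls Bcl6 did not part that way, at 9.19 in the one with high Cish and 8.47 to 9.57 in the rest. The 2 clusters were found in these same livers, so the explanation is left open, and a pulse caught in single livers was tested through its relation to other genes at day 10 less group means. Its r was -0.152 with Socs2 (n = 10, permutation p = 0.610, adjusted p = 0.813) and -0.0661 with Bcl6 (n = 10, permutation p = 0.910, adjusted p = 0.910), so neither passed. Across the 18 liver arrays of both times, where the day 4 livers form 2 clusters, r was 0.379 with Socs2 (permutation p = 0.0803, adjusted p = 0.321; rho 0.496, permutation p = 0.0261, adjusted p = 0.104) and -0.284 with Bcl6 (permutation p = 0.244, adjusted p = 0.487), and neither passed.

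Other lists made after the results were seen were smooth muscle markers in adipose tissue (median 0.54, camera p = 0.0131, p = 0.443 with an estimated correlation), lymphatic vessel markers (adipose tissue 0.29, camera p = 0.401) and mesothelium markers (adipose tissue 0.01, camera p = 0.563). Genes induced by a growth hormone pulse were not called by camera in liver, with a median of 1.49 at day 4 and 0.28 at day 10.

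The 57 control probe sets were fitted apart from the others by limma and adjusted over these 57 alone. In this fit 6 were called in liver at day 4, 3 at day 10 and 0 in adipose tissue. All of them measure rat transcripts: actin and Gapdh at day 4 (-0.40 to -0.68) and actin at day 10 (-0.31 to -0.40). The 3' minus 5' signals of actin and Gapdh had exact permutation p between 0.0556 and 0.657.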
